A study of Mus musculus with 14 samples.

How the data were processed

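RNA sequencing was made from 14 tubes of mouse neurons. Each tube held 4 to 5 EGFP-labelled PiC neurons of C57BL/6 mice, collected with a micropipette whose tip was 60 to 100 µm wide and amplified with SMART-Seq2, a method that reads polyadenylated RNA over its full length. The neurons had been labelled from their targets by 0.1 µl of AAVretro-EGFP, a virus that travels back along axons to the cell body, placed in PrL or MeA. The abbreviations PiC, PrL and MeA are used as the labels give them. The groups were female PiC-PrL (n = 4), male PiC-PrL (n = 4), female PiC-MeA (n = 3) and male PiC-MeA (n = 3). The labels do not say that the tubes came from separate animals, so every p-value here measures only the spread between these samples. No batch, date or age is given in the sources used here. Correlations of expression residuals over 19 pairs of libraries with the same replicate number lay between -0.0486 and 0.0496, so no pairing across groups was seen. Without a reference for paired tubes of 4 to 5 cells, pairing is not excluded.

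The deposited table holds raw counts per gene, in 1 column per library, which the authors made without pooling or normalisation. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, SAMtools, featureCounts 2.0.1 and the genome build mm10. The annotation release, the strand setting and the handling of reads shared between genes are not given in the sources used here. The table lists 55401 genes, of which 54349 have the same versioned identifier in GENCODE M21 and 55141 match without the version. Gene names, positions and 3' UTR lengths were taken from that release. No column belonged to other samples. Total counts ran from 6132985 to 15392217 per library. For a gene with no counts, 3 counts per library were taken as the highest level that a count of 0 allows, and such floors and intervals cover counting error only.

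Genes were kept by the filterByExpr function of edgeR with a minimum count of 10 and a minimum total of 15, which left 14599. Counts were normalised by the trimmed mean of M-values (TMM) and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group. The 7 contrasts were sex within each projection, sex averaged over both projections, projection within each sex, projection averaged over both sexes, and the difference between the sex differences. Sex contrasts are male minus female and projection contrasts are PiC-MeA minus PiC-PrL. A gene passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Levels are counts scaled to a common library total (CPM) with the TMM factors, given as mean ± SD, and fold changes are log2 values ± SE. Quality measures of the libraries were compared by exact two-sided permutation tests, adjusted over the family of 20 tests, which were chosen after the quality values were seen.

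A set of 39 gene lists was written down, and the 37 with at least 5 tested genes were compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01. No list call at the preset correlation was kept with a correlation estimated per list, and that adjusted p stands beside each call. The fry function was run as well, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Members of a list were also adjusted over the list alone. List medians are over fitted changes, which for members at 0 counts in a group depend on the prior count of the fit.

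The grouping, the model, the lists, the rule for named genes and most alternatives were chosen before the data were examined. For sex within each projection and for the average projection contrast, the rule named up to 8 genes per direction with the smallest p among those that passed with at least 10 counts in every library of the higher group. It left out Y-linked genes, Xist, predicted genes and pseudogenes, and where none passed it took the 3 with the smallest p. It added up to 4 members per list that passed. The other contrasts took up to 4 genes per direction under the same conditions. Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Esr1, Esr2, Pgr, Cyp19a1 and Nr3c1 were always given for the sex contrasts. A few genes named by the rule, none of which passed, are not reported here. Other genes in the text were chosen after their values were seen, among them marker genes and members that passed adjusted over the list alone.

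The alternatives were DESeq2 size factors, no filter, a stricter filter of 10 counts in 7 libraries, the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit without the robust option, a fit of only the groups compared, the number of detected genes as a covariate, a block for the replicate number and leaving out each library. Added after seeing the data were a fit without the 3 male PiC-MeA libraries, a fit without the 3 PiC-PrL libraries that had the fewest genes at 10 counts, and removal of each library's trend with gene span. That trend was first removed with no centring, which also rescaled whole libraries. A centred version was defined after this had been seen, and both are reported. Each contrast was also refitted on other splits of the samples, at most 100 per contrast.

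The model was tested on simulated data, with 200 genes changed in each of 5 runs. For the average projection contrast edgeR recovered 0.8% of genes changed by 2-fold, 6.8% at 4-fold, 23.2% at 8-fold and 45.6% at 32-fold. For sex in PiC-PrL it recovered 24.4% at 32-fold and for sex in PiC-MeA 18.8%. Unchanged genes called numbered at most 9 in any of the 5 runs by edgeR, and 1 to 4 by voom and 174 to 230 by DESeq2, which were each given 1 run per contrast. Apart from the changed genes, simulated counts had 1 mean per gene over all 14 libraries and the spread that edgeR had estimated. They lack the larger number of detected genes in male PiC-MeA libraries. These rates therefore do not give the error rates in the real data and do not rank the methods there. Tables were prepared with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.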

Results

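Gene expression was measured in PiC neurons that had been labelled from PrL or from MeA, in female and male mice. The series names networks of transcription factors and sex hormones in sexually dimorphic expression as its subject, and the 4 groups allow sex to be compared within each projection and the projections within each sex. Total counts in female PiC-PrL libraries were 12077736, 14374024, 13285882 and 15392217 for replicates 1 to 4. The male PiC-PrL libraries held 15225936, 14274982, 14674376 and 14599391 counts. Female PiC-MeA libraries held 11755389, 12846359 and 13818625 counts, and male PiC-MeA libraries held 10572618, 10515270 and 6132985. The 3 male PiC-MeA libraries had at least 1 count for 18964 to 20014 genes, against 12479 to 14908 in the other 11 libraries. Spearman correlations across genes were 0.686 to 0.777 between libraries of 1 group and 0.639 to 0.776 between groups, and genes are not independent replicates.

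**Figure D1:**
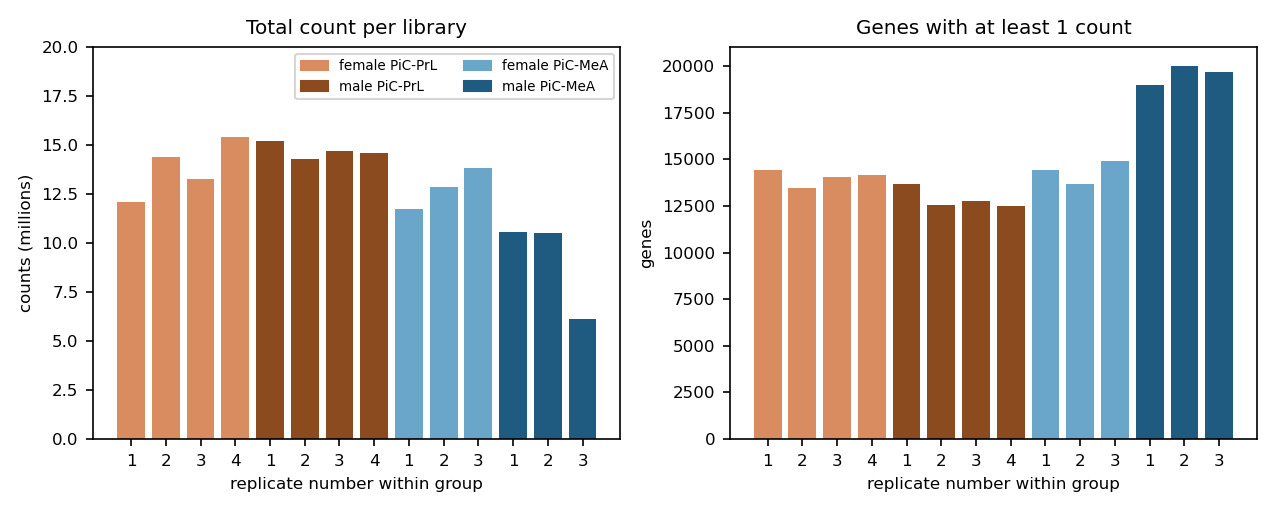
Total count and number of genes with at least 1 count (y axes) for each replicate (bars) of the 4 groups. The 3 male PiC-MeA libraries lie between 18964 and 20014 genes, above the other 11 libraries, and hold the 3 smallest totals.

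The Y-linked genes Eif2s3y and Ddx3y separated the sexes as labelled, while Kdm5d and Uty did so in PiC-MeA but not in PiC-PrL libraries. Eif2s3y, a translation initiation factor subunit (Y, 1010543 to 1028847), had at least 136 counts in every male library and at most 3 in any female library. Its level was 98.3 ± 53.8 CPM in male PiC-PrL neurons (n = 4) and 74.3 ± 49.997 CPM in male PiC-MeA neurons (n = 3). Ddx3y, an RNA helicase, reached 62.3 ± 41.4 CPM in male PiC-PrL neurons with only 9 counts in replicate 3, and 102 ± 57.1 CPM in male PiC-MeA neurons, at least 460-fold higher than in female PiC-MeA libraries, which held 0 counts. The histone demethylase gene Kdm5d had 0 counts in some male PiC-PrL libraries and 39 to 162 counts in male PiC-MeA libraries, against 0 in female PiC-MeA libraries. Uty, a related demethylase gene, had 0 to 383 counts in male PiC-PrL libraries and 89 to 529 in male PiC-MeA libraries. Female PiC-PrL libraries held 2 to 4 counts of Uty and female PiC-MeA libraries 0 to 2. Xist, the transcript that coats the inactive X chromosome, was listed at 0 in all 14 libraries, as was its antisense partner Tsix, so it could not serve as a check of the female labels. Exons of Xist and Tsix overlap, and how reads in overlaps were counted is not given in the sources used here, so these 0 counts do not show that the transcripts were absent.

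Sex in PiC-PrL neurons was compared between 4 male and 4 female libraries, and no gene passed. The genes with the smallest p that were higher in males were Tspan7, Cln8 and Tacc1. Tspan7, a membrane protein of the tetraspanin family (X, 10485158 to 10596605), stood at 2419 ± 622 CPM in males and 944 ± 171 CPM in females (log2 1.36 ± 0.29, adjusted p = 0.283). Tacc1, a coiled-coil protein of microtubules, stood at 592 ± 321 against 190 ± 62.8 CPM, and Cln8, an endoplasmic reticulum protein, had at most 1 count in any female library and 35.7 ± 28.2 CPM in males. Lower in males with the smallest p were Gpkow, Mtmr3 and Zfp697. The RNA-binding protein Gpkow (X, 7697131 to 7710262) was at 64.8 ± 43.2 CPM in females and had 0 to 4 counts per male library (adjusted p = 0.207). Mtmr3, a phosphoinositide phosphatase, was at 111 ± 40.8 against 3.45 ± 2.69 CPM, and Zfp697 at 37.0 ± 23.9 against 0.271 ± 0.150 CPM. Of genes differing between male and female PiC-PrL neurons, edgeR called 0 of 14599, 2093 had an unadjusted p under 0.05, the DESeq2 Wald test called 1017 and limma voom 8. The count was 1 without female PiC-PrL replicate 1 or without female PiC-MeA replicate 1, 2 or 3. All 4 Y-linked genes passed when adjusted over the list alone.

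Steroid receptors, the group nearest to the stated subject, gave no call in PiC-PrL neurons. Of 10 tested members, 8 had a positive and 2 a negative fitted change (median 0.65, camera adjusted p = 0.373, fry adjusted p = 0.330), and none passed adjusted over the list alone. Esr1, estrogen receptor alpha (10, 4611593 to 5005614), gave a log2 of -4.16 ± 1.97 (adjusted p = 0.346), a value that rests on the 780 counts of female PiC-PrL replicate 3. The other female PiC-PrL libraries held 4 to 11 counts, and without that library the fitted change of Esr1 was 0.21. The progesterone receptor gene Pgr gave 1.17 ± 1.61 (adjusted p = 0.852) and the glucocorticoid receptor gene Nr3c1 gave 0.12 ± 0.97 (adjusted p = 0.991). Cyp19a1, which encodes aromatase, had at most 1 count in any PiC-PrL library. Esr2, estrogen receptor beta, had at most 5 counts per PiC-PrL library and was not tested. Estrogen-responsive genes had a median of -1.11 over 21 members (7 positive and 14 negative, camera adjusted p = 0.106), and androgen- or glucocorticoid-responsive genes a median of -0.27 over 15 (camera adjusted p = 0.538).

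**Figure D2:**
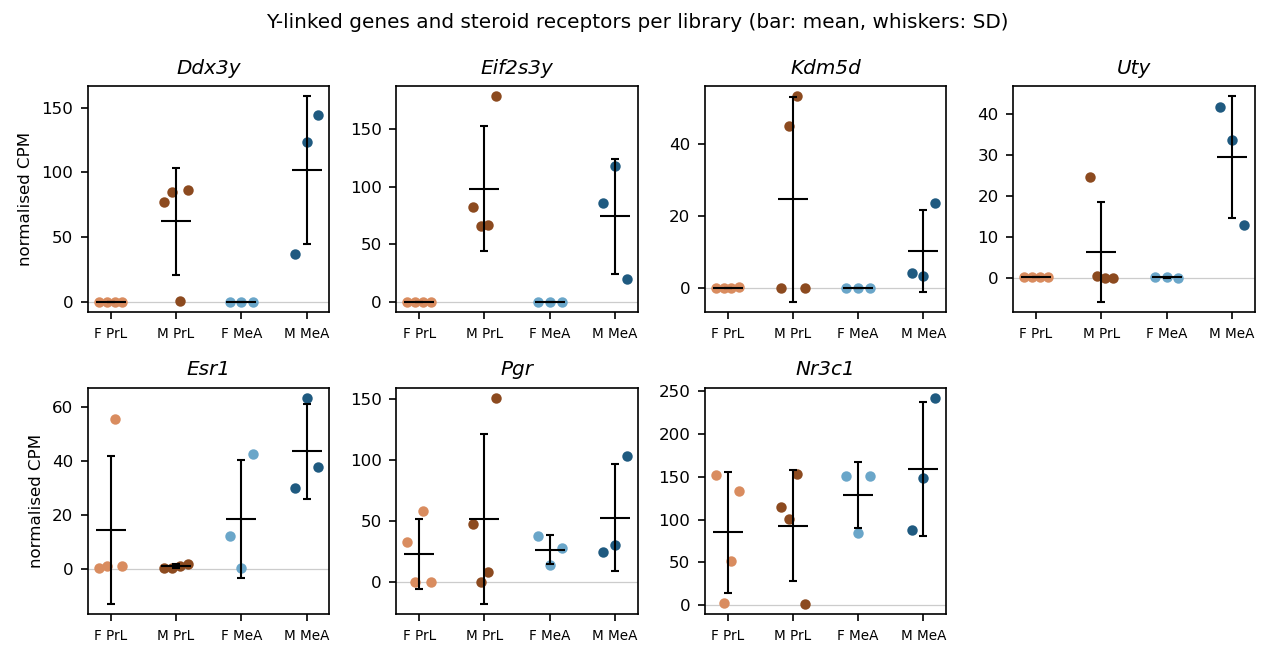
Normalised CPM (y axes) of 4 Y-linked genes and of Esr1, Pgr and Nr3c1, with 1 dot per library, a bar at the mean and whiskers for the SD in each of the 4 groups. Eif2s3y separates male from female libraries, and Esr1 in female PiC-PrL neurons is set by 1 library at 55.6 CPM.

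Of 37 gene lists, 6 differed in rank between male and female PiC-PrL neurons by camera at the preset correlation, and none with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain of mitochondria, had positive fitted changes in 71 of 85 members (median 0.32, camera adjusted p = 0.00133, adjusted p = 0.436 with an estimated correlation). The proteasome, which degrades proteins, had 29 of 37 positive (median 0.40, camera adjusted p = 0.00842, adjusted p = 0.363 with an estimated correlation). Cholesterol synthesis had 13 of 20 positive (median 0.35). Axon guidance genes had 36 of 50 negative (median -0.87), chromatin modifiers 45 of 67 (median -0.47), and potassium and HCN channels 35 of 52 (median -0.42). These last 4 lists each had a camera adjusted p of 0.0309 and an adjusted p of 0.358 with an estimated correlation. Adjusted over the list alone, Epha6 was lower in males (log2 -2.46) and no other member of these 6 lists passed. Inhibitory neuron markers, which missed the call (median -0.96, camera adjusted p = 0.0625), included Npy at log2 -5.69 and Erbb4 at -3.80, both past the threshold adjusted over the list alone. Other cell classes that missed the call were oligodendrocyte precursor markers (7 of 8 negative, median -2.86, camera adjusted p = 0.0689), microglia markers (12 of 15 positive, camera adjusted p = 0.0729) and astrocyte markers (12 of 18 positive, camera adjusted p = 0.0931). All 4 tested red blood cell genes were positive, too few for a test of the list. Gad1, the enzyme of GABA synthesis, was at 329 ± 410 CPM of total counts in female and 22.6 ± 21.02 CPM in male PiC-PrL libraries. In female replicates 1 to 4 Gad1 stood at 914, 37.4, 49.6 and 314 CPM and Npy at 1549, 13.6, 115 and 3081 CPM. Male libraries reached 49.7 and 45.3 CPM, so these differences rest mainly on female replicates 1 and 4. Erbb4 was at 136 CPM or more in female and at most 41.0 in male PiC-PrL libraries. The number of lists called was 6, 3 without female PiC-PrL replicate 4, 11 without female PiC-PrL replicate 1, 1 without the 3 PiC-PrL libraries with the fewest genes, and 10 without the male PiC-MeA libraries. With the gene span trend removed none of the 6 lists was called.

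Sex in PiC-MeA neurons was compared between 3 male and 3 female libraries, and no gene passed here either. Slc1a2, the main glutamate transporter of astrocytes (2, 102658659 to 102790784), stood at 750 ± 129 CPM in males and 213 ± 83.6 CPM in females (log2 1.82 ± 0.39, adjusted p = 0.298). Zbtb20, a zinc finger transcription factor, stood at 159 ± 55.0 against 13.5 ± 4.32 CPM, and Lrp1b, a receptor of the LDL receptor family, at 838 ± 5.03 against 251 ± 124 CPM. Gabarapl1, a protein of autophagosomes (6, 129533160 to 129542346), was at 170 ± 44.2 CPM in males and 737 ± 109 CPM in females (log2 -2.12 ± 0.36, adjusted p = 0.106). Dusp3, a phosphatase that acts on MAP kinases, was at 122 ± 26.8 against 371 ± 138 CPM, and Nudt3, a nudix hydrolase, at 66.1 ± 14.5 against 248 ± 64.9 CPM. By edgeR 0 genes passed and 1805 had an unadjusted p under 0.05, of which 1506 were higher in males, while DESeq2 called 777 and voom 1761. The count was 14 without male PiC-MeA replicate 1. Eif2s3y (adjusted p = 0.106) and the other 3 tested Y-linked genes passed adjusted over the list alone.

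The male PiC-MeA libraries differed from the female PiC-MeA libraries in several measures that move with this comparison. They held 19557 ± 538 genes with a count against 14334 ± 623 in female PiC-MeA libraries, a difference of 5222 with an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. The difference between the sex differences of the projections was 6365 genes (exact permutation p = 0.00286, adjusted p = 0.0571 over 20 tests). The permutations moved sex labels within each projection, so this p is for no sex difference in either projection, not for equal sex differences. The mitochondrial share of counts was 4.80%, 9.23% and 15.3% in the male and 3.29% to 3.95% in the female PiC-MeA libraries. PiC-PrL libraries ranged from 3.81% to 12.2%, so this share did not set male PiC-MeA libraries apart from those. Olfactory receptor genes with a count numbered 204 to 268 of 1117 in male PiC-MeA libraries and 39 to 78 in the other 11.

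Steroid receptors in PiC-MeA neurons had 9 positive and 1 negative fitted change (median 1.11, camera adjusted p = 0.397), and none passed adjusted over the list alone. By fry, which does not compare a list with other genes, they moved up (adjusted p = 0.0163), as 1 of 13 lists that passed by fry, 9 of them up. The median fell to 0.34 with the gene span trend removed and to -0.43 with the uncentred removal, where the median of all genes was -0.75. Esr1 gave 1.249 ± 2.02, Pgr 0.98 ± 1.85 and Nr3c1 0.31 ± 1.12, each with an adjusted p of 1.0. Cyp19a1 had 11 to 83 counts in male and at most 3 in female PiC-MeA libraries (adjusted p = 0.341). Esr2 had 5 to 111 counts in male and at most 2 in female PiC-MeA libraries and was not tested. The same male libraries held counts for 204 to 268 olfactory receptor genes, against 39 to 78 in the others. Whether the low counts of Cyp19a1 and Esr2 belong to that excess was not tested. With the number of detected genes as a covariate, the log2 of Cyp19a1 went from 4.87 to 0.46 ± 1.84. Estrogen-responsive genes had a median of -0.57 and a mean of 1.24 over 21 members (camera adjusted p = 0.890), and androgen- or glucocorticoid-responsive genes a median of -0.04 over 15 (camera adjusted p = 0.596).

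Several gene groups ranked lower in male than in female PiC-MeA neurons. Nuclear-encoded oxidative phosphorylation genes were negative in 73 of 85 members (median -0.72, camera adjusted p = 7.48e-16), cytosolic ribosomal proteins in 72 of 76 (median -0.77, camera adjusted p = 7e-15) and proteasome subunits in 34 of 37 (median -0.92, camera adjusted p = 6.97e-10). Pan-neuronal genes were negative in 14 of 18 (median -0.55, camera adjusted p = 0.000728). Each of these 4 had an adjusted p = 0.137 with an estimated correlation, and none of their members passed, over all genes or over the list alone. Immediate early genes, which respond to neuronal activity, were negative in 23 of 30 (median -0.76, camera adjusted p = 0.00176, adjusted p = 0.333 with an estimated correlation). Heat shock genes were negative in 18 of 26 (median -0.67, camera adjusted p = 0.0204, adjusted p = 0.257 with an estimated correlation). Excitatory neuron markers were negative in 10 of 14 with a median of -0.37 but a mean of 0.12 (camera adjusted p = 0.0214, adjusted p = 0.244 with an estimated correlation). All 7 of these lists moved beside the larger number of genes detected in male PiC-MeA libraries, 19557 against 14334.

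Markers of some other cell classes and mitochondrial transcripts ranked higher in male PiC-MeA neurons. Oligodendrocyte, oligodendrocyte precursor and microglia markers were not called (camera adjusted p = 0.908, 0.890 and 0.890). Mitochondrially encoded genes were positive in 32 of 32 members (median 1.91, camera adjusted p = 3.3e-07, adjusted p = 0.267 with an estimated correlation), and 7 passed adjusted over the list alone. Inhibitory neuron markers were positive in 19 of 22 (median 3.01, camera adjusted p = 0.00150, adjusted p = 0.307 with an estimated correlation), with Gad1, Vip and Adarb2 past the threshold adjusted over the list alone. Astrocyte markers were positive in 13 of 18 (median 1.22, camera adjusted p = 0.00205, adjusted p = 0.244 with an estimated correlation), with Slc1a2, Slc4a4, Gjb6, Slc1a3 and Aqp4 past the threshold adjusted over the list alone. Endothelial and mural markers were positive in 10 of 12 (camera adjusted p = 0.00426, adjusted p = 0.137 with an estimated correlation), with Pdgfrb past it. Of total counts, the astrocyte water channel Aqp4 was at 93.0 ± 69.0 CPM in male and 0 in female PiC-MeA libraries, and Gad1 at 379 ± 475 against 12.99 ± 18.2 CPM. In male replicates 1 to 3 Gad1 stood at 33.5, 183 and 920 CPM and Vip at 0.0946, 30.8 and 415 CPM. Female libraries reached 33.9 and 0.170 CPM, so these rises rest on male replicates 2 and 3. Adarb2 was at 76.7 CPM or more in male and at most 22.7 in female libraries. Over these male replicates Camk2a went from 2002 to 610 and 179 CPM and Slc17a6 from 0.284 to 285 and 634. Cell content of the tubes was not tested apart from sex. The number of lists called was 11, and between 10 and 14 with any 1 library left out. With the gene span trend removed 16 lists were called and 10 of the 11 kept their call, heat shock genes being the exception with a median of -0.11. The medians of ribosomal, immediate early and oxidative phosphorylation genes shrank to -0.26, -0.39 and -0.37. Those of pan-neuronal and mitochondrially encoded genes grew to -0.70 and 2.46. Among lists newly called lower, glutamate receptors turned from a median of 0.35 to -0.68 and postsynaptic genes from 0.37 to -0.61.

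**Figure D3:**
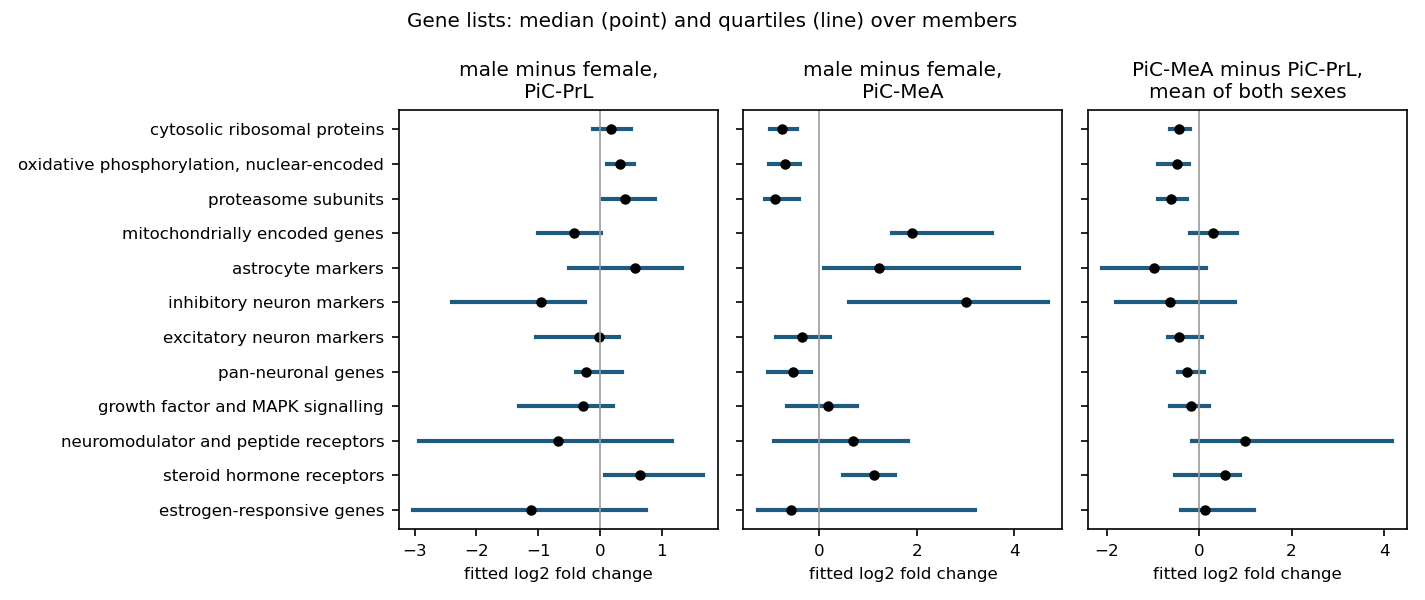
Fitted log2 fold changes (x axis) over the members of 12 gene lists, with a point at the median and a line over the quartiles, for sex in PiC-PrL, sex in PiC-MeA and the average projection contrast (panels). In PiC-MeA neurons the medians of ribosomal, oxidative phosphorylation and proteasome lists were -0.77, -0.72 and -0.92, and that of mitochondrially encoded genes 1.91.

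Averaged over both projections, the Y-linked genes Eif2s3y (adjusted p = 0.00245) and Ddx3y (adjusted p = 0.0373) rose in males and no gene fell. Of other genes, Il1rapl2, a relative of synaptic adhesion molecules, had a log2 of 2.21, Slc1a2 of 0.96, Actb, cytoplasmic actin, of -1.07 and Nudt3 of -1.20, each at an adjusted p of 0.275. Deptor, an inhibitor of mTOR, and Gpkow had the same adjusted p with a group near 0 counts. At an unadjusted p under 0.05 there were 1557 genes. As the count of genes differing between males and females, averaged over both projections, DESeq2 gave 631 and voom 4. The count was 1 without any 1 of 11 libraries, the exceptions being female PiC-PrL replicates 1 and 4 and male PiC-PrL replicate 3, and 1 without the 3 PiC-PrL libraries with the fewest genes.

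In the count of genes whose sex difference differs between the projections, no gene passed. Genes with the smallest p, each at an adjusted p of 0.152, were Pde10a, a phosphodiesterase (log2 4.11 ± 0.83), Zbtb20 (5.22 ± 1.08), Gabarapl1 (-2.62 ± 0.47), Dusp3 (-2.16 ± 0.43) and Mex3c, an RNA-binding ubiquitin ligase with 0 to 2 counts in female PiC-MeA libraries. Zbtb20 was at 326 ± 368 CPM in female and 103 ± 50.1 CPM in male PiC-PrL neurons, the opposite order from PiC-MeA neurons. By edgeR 0 genes passed, 2272 had an unadjusted p under 0.05, DESeq2 called 1175 and voom 729. The count was 5 without male PiC-MeA replicate 1 and 1 without female PiC-PrL replicate 1 or male PiC-PrL replicate 1. The sex differences of ribosomal, oxidative phosphorylation and proteasome lists differed between the projections by medians of -0.95, -1.10 and -1.09 (camera adjusted p = 3.05e-11, 5.51e-15 and 1.14e-09, each with an adjusted p of 0.320 with an estimated correlation). These lists moved beside the larger number of genes detected in male PiC-MeA libraries. For sex in PiC-MeA the ribosomal median went from -0.77 to -0.26 with the gene span trend removed.

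By edgeR in the main fit, projection target averaged over both sexes gave more calls than sex. With voom it gave fewer than sex in PiC-MeA neurons, with the detected-gene covariate it gave none, and projection within females alone gave none by edgeR in the main fit. Compared with PiC-PrL neurons, 92 genes were lower and 28 higher in PiC-MeA neurons. Dusp3 (11, 101971143 to 101987013, ENSMUSG00000003518.13) fell by 2.41 ± 0.23 on the log2 scale (adjusted p = 8.1e-05), from 933 ± 71.0 CPM in female and 1377 ± 264 CPM in male PiC-PrL neurons to 371 ± 138 and 122 ± 26.8 CPM in PiC-MeA neurons. Gnb1, a beta subunit of heterotrimeric G proteins (4, 155491361 to 155559269, ENSMUSG00000029064.15), fell by 2.14 ± 0.21 (adjusted p = 8.1e-05). Its level was 6819 ± 2070 and 8679 ± 2894 CPM in female and male PiC-PrL neurons and 2172 ± 418 and 1406 ± 309 CPM in PiC-MeA neurons. Klf13, a zinc finger transcription factor (log2 -2.28 ± 0.27), Inpp4a, an inositol phosphatase (-2.32 ± 0.28), Prune2 (-2.46 ± 0.30) and Nmt2, which adds myristate to proteins (-2.15 ± 0.26), each fell with an adjusted p of 0.000464. Dpysl2, a tubulin-binding protein of growing axons, fell by 1.67 ± 0.20 and Cask, a synaptic scaffold, fell by 2.14 ± 0.28. Each was lower in every PiC-MeA library than in any PiC-PrL library, and the calls of these 8 genes were kept with any 1 library left out.

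**Figure D4:**
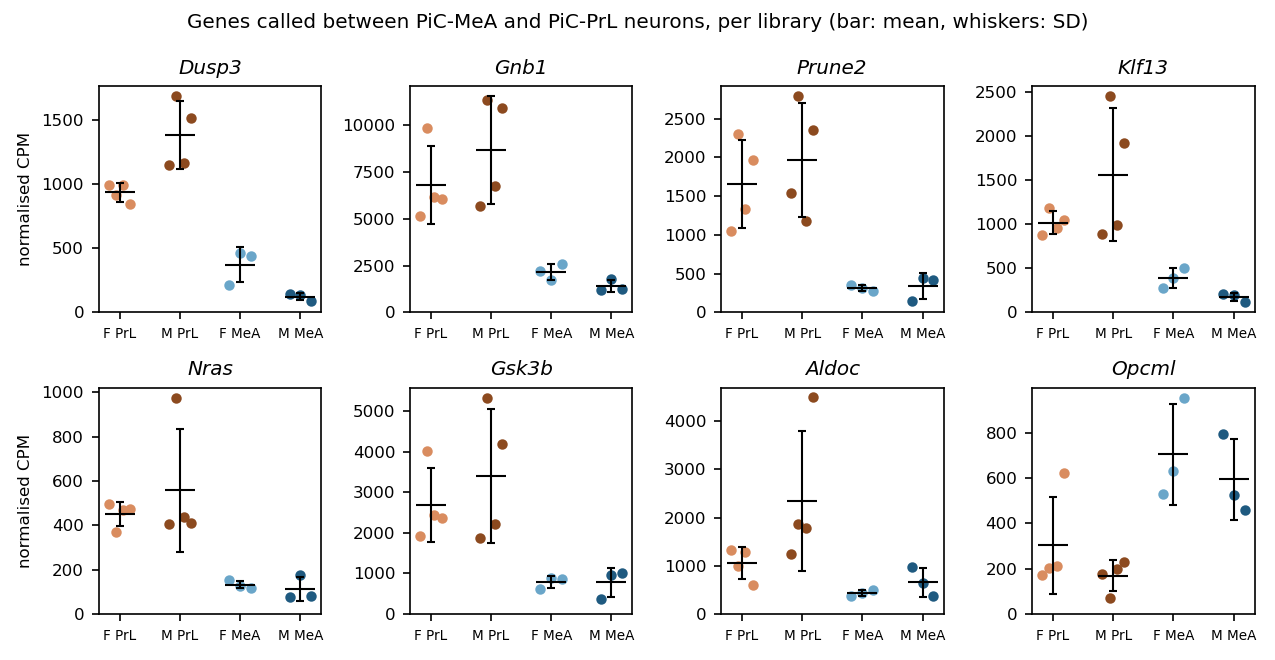
Normalised CPM (y axes) of Dusp3, Gnb1, Prune2, Klf13, Nras, Gsk3b, Aldoc and Opcml, with 1 dot per library, a bar at the mean and whiskers for the SD in each of the 4 groups. Dusp3 averaged 933 and 1377 CPM in PiC-PrL neurons against 371 and 122 CPM in PiC-MeA neurons, while Opcml averaged 303 and 169 against 704 and 594.

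Among genes higher in PiC-MeA neurons, Opcml, a cell adhesion molecule anchored in the membrane (9, 27790775 to 28925410), rose by 1.51 ± 0.33 on the log2 scale (adjusted p = 0.0455), from 303 ± 214 and 169 ± 67.9 CPM to 704 ± 224 and 594 ± 178 CPM in females and males. The other named genes that rose were at or near 0 in PiC-PrL libraries. Snhg17, a noncoding host of small nucleolar RNAs, had 0 counts in every PiC-PrL library and was at least 30.9-fold higher in PiC-MeA neurons (adjusted p = 0.0259). Pfn4, a profilin, had at most 1 count per PiC-PrL library and 44 to 387 per PiC-MeA library (adjusted p = 0.0156). Ptpn21, a tyrosine phosphatase, and Selenon, a selenoprotein, had at most 2 counts per PiC-PrL library (adjusted p = 0.0345 and 0.0490). Calls ended in 13 of 14 single-library omissions for Opcml and Ptpn21, 14 for Selenon, 8 for Snhg17 and 0 for Pfn4. The call of Opcml also ended with both removals of the gene span trend, and that of Selenon with the centred removal. Both ended without the robust option. Each of these genes lost its call without the 3 PiC-PrL libraries with the fewest genes. Exons of Dusp3, Pfn4 and Snhg17 overlap exons of another annotated gene, and 15 of 61 named genes do so in all.

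Growth factor and MAPK signalling genes ranked lower in PiC-MeA neurons. Of 43 members 4 fell and none rose, over all genes and adjusted over the list alone. These were Dusp3, Nras, a small GTPase (log2 -2.05 ± 0.30, adjusted p = 0.00198), the kinase Gsk3b (-1.95 ± 0.29, adjusted p = 0.00249) and Spry2, an inhibitor of receptor tyrosine kinase signalling (-2.45 ± 0.44, adjusted p = 0.0146). The list median was -0.18 with 25 members negative (camera adjusted p = 0.00439, adjusted p = 0.0695 with an estimated correlation). Forebrain transcription factors were negative in 29 of 50 (median -0.33, camera adjusted p = 0.00677, adjusted p = 0.0802 with an estimated correlation). Lmo4, a LIM-domain regulator, fell by 1.52 ± 0.29 (adjusted p = 0.0198) and Nfib fell by 1.249 ± 0.29 (adjusted p = 0.0497), and adjusted over the list alone 1 member was higher and 3 lower. Pan-neuronal genes were negative in 12 of 18 (median -0.26, camera adjusted p = 0.00730, adjusted p = 0.220 with an estimated correlation), with Snap25, a SNARE protein of synaptic vesicle fusion, falling by 0.86 ± 0.18 (adjusted p = 0.0363). Adjusted over that list alone 1 was higher and 3 lower. The calls of Nras, Gsk3b and Spry2 were kept with any 1 library left out, while those of Lmo4, Nfib and Snap25 ended in 2, 11 and 5 of 14 omissions. With the replicate block, and without the 3 PiC-PrL libraries with the fewest genes, the calls of Spry2, Lmo4, Nfib and Snap25 ended.

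Astrocyte markers were negative in 13 of 18 members (median -0.97, camera adjusted p = 0.000116, adjusted p = 0.124 with an estimated correlation). Glul, glutamine synthetase, fell by 2.31 ± 0.46 and Aldoc, an aldolase of glycolysis, by 1.57 ± 0.31 (both adjusted p = 0.0248), and the same 2 genes passed adjusted over the list alone. Aldoc was at 1055 ± 339 and 2344 ± 1458 CPM in female and male PiC-PrL neurons and at 428 ± 64.4 and 659 ± 300 CPM in PiC-MeA neurons. Another astrocyte marker, Slc1a2, was at 628 ± 178 and 671 ± 248 CPM in PiC-PrL neurons, 213 ± 83.6 in female and 750 ± 129 in male PiC-MeA neurons. The calls of Aldoc and Glul ended in 4 and 6 of 14 single-library omissions. Both also ended with the replicate block and without the 3 PiC-PrL libraries with the fewest genes.

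Housekeeping groups also ranked lower in PiC-MeA neurons on average, with lower medians in males and medians near 0 in females. The medians of the oxidative phosphorylation, proteasome and ribosomal lists were -1.07, -1.16 and -0.87 in males. In females they were -0.015, -0.041 and 0.041 (camera adjusted p = 0.752, 0.832 and 0.961). The male PiC-MeA libraries also stood apart in the number of genes with a count. Averaged over both sexes, oxidative phosphorylation genes were negative in 71 of 85 (median -0.48, camera adjusted p = 3.06e-16, adjusted p = 0.0954 with an estimated correlation). Sdhb of complex II (log2 -1.16 ± 0.23), Ndufa12 of complex I (-1.34 ± 0.27) and Uqcrq of complex III (-1.31 ± 0.26) fell with an adjusted p of 0.0248 and Ndufb8 of complex I with 0.0497, and adjusted over the list alone 15 were lower and 1 higher. Proteasome subunits were negative in 33 of 37 (median -0.60, camera adjusted p = 3.27e-10, adjusted p = 0.0802 with an estimated correlation), with Psmb6 falling by 1.47 ± 0.31 (adjusted p = 0.0358) and 4 lower adjusted over the list alone. Cytosolic ribosomal proteins were negative in 66 of 76 (median -0.43, camera adjusted p = 1.82e-09, adjusted p = 0.220 with an estimated correlation), with Rps14 falling by 1.29 ± 0.29 (adjusted p = 0.0490). With the gene span trend removed the ribosomal median was 0.01, with the list still called lower (camera adjusted p = 0.0337), while those of the oxidative phosphorylation and proteasome lists were -0.31 and -0.59. The mitochondrial transcript mt-Cytb, for cytochrome b, fell by 1.70 ± 0.39 (adjusted p = 0.0490) while its list had a median of 0.30 over 32 members (camera adjusted p = 0.975). With the span trend removed that list was called higher (median 1.28, camera adjusted p = 0.000213). In female PiC-PrL replicate 2 mitochondrial transcripts made up 12.2% of counts, and the call of mt-Cytb ended in 10 of 14 single-library omissions. The calls of Sdhb, Ndufa12, Uqcrq, Ndufb8, Psmb6 and Rps14 ended in 6, 7, 7, 12, 9 and 10. Each of these calls and that of mt-Cytb also ended with the replicate block and without the 3 PiC-PrL libraries with the fewest genes. Those of Uqcrq, Ndufb8, Psmb6 and mt-Cytb ended with the centred removal of the gene span trend as well.

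Neuromodulator and peptide receptors were the only list called higher in PiC-MeA neurons, with 36 of 53 members positive (median 1.00, camera adjusted p = 0.0107, adjusted p = 0.0695 with an estimated correlation). The median was 2.11 in males (camera adjusted p = 0.0292, adjusted p = 0.0648 with an estimated correlation), whose PiC-MeA libraries held counts for more genes than any other. In females it was 0.31 (camera adjusted p = 0.501). No member passed over all genes by edgeR, and 9 passed adjusted over the list alone. These were the receptors Ntsr1 for neurotensin, Lepr for leptin, Drd2 and Drd3 for dopamine, Htr5a, Htr4, Crhr2, Sstr1 and Mc4r. Without centring, removal of the gene span trend gave this list a median of -0.16, where the median of all genes was -0.79. Of other lists, the interferon gene Ifit1 (adjusted p = 0.0435), Zfp758 (adjusted p = 0.0347) and Zfp455 (adjusted p = 0.0405) were higher with at most 2 counts in any PiC-PrL library. Single PiC-MeA libraries held as few as 1 count of Ifit1 and of Zfp455, and the calls of these 3 genes ended in 14, 12 and 14 of 14 single-library omissions. Steroid receptors had 7 positive and 3 negative members (median 0.56, camera adjusted p = 0.733, fry adjusted p = 0.0285), and none passed adjusted over the list alone.

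The number of genes differing between PiC-MeA and PiC-PrL neurons, averaged over both sexes, depended on the test and on single libraries. At an unadjusted p under 0.05 there were 2543 genes, of which 1773 were higher in PiC-MeA neurons, and the 92 lower against 28 higher of edgeR became 531 lower and 961 higher with DESeq2 and 250 lower and 1027 higher with voom. The count of 120 was 68 without female PiC-PrL replicate 2, 45 and 53 without male PiC-PrL replicates 2 and 4, 54, 39 and 57 without female PiC-MeA replicates 1, 2 and 3, and 47 and 48 without male PiC-MeA replicates 2 and 3. It was 31 without the 3 PiC-PrL libraries with the fewest genes, which were female replicate 2 and male replicates 2 and 4, and 0 with the number of detected genes as a covariate. The covariate widened the error of Dusp3 from 0.23 to 0.84 around a log2 of -1.78.

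Within males, 78 genes were lower and 10 higher in PiC-MeA than in PiC-PrL neurons. Dusp3 fell by 3.49 ± 0.35 (adjusted p = 0.000140), Gnb1 by 2.63 ± 0.31 (adjusted p = 0.000623) and Nmt2 by 3.03 ± 0.38 (adjusted p = 0.000962). Zwint, a kinetochore protein, fell by 1.73 ± 0.22 (adjusted p = 0.000962), from 5534 ± 407 to 1672 ± 332 CPM. Il1rapl1, a synaptic adhesion molecule, rose by 2.53 ± 0.52 (adjusted p = 0.0360), from 142 ± 49.3 to 816 ± 482 CPM, and Dok6, an adaptor of receptor tyrosine kinases, by 2.94 ± 0.61 (adjusted p = 0.0373), from 30.2 ± 14.99 to 232 ± 74.7 CPM. Gpkow and Zfp697 also rose (adjusted p = 0.0219 and 0.0327), with 0 to 4 and 1 to 7 counts in male PiC-PrL libraries. The calls of Il1rapl1, Dok6, Gpkow and Zfp697 ended in 10, 10, 4 and 8 of 14 single-library omissions, and those of Il1rapl1 and Dok6 also with both removals of the gene span trend. That of Zfp697 ended with the centred removal. Each of these calls also ended with the replicate block and without the 3 PiC-PrL libraries with the fewest genes. The larger number of genes with a count in male PiC-MeA libraries, 6688 above male PiC-PrL libraries (exact permutation p = 0.0286, adjusted p = 0.0952 over 20 tests), moves with this comparison. The count of 88 genes differing between PiC-MeA and PiC-PrL neurons of males was 20, 58 and 29 without male PiC-PrL replicates 2, 3 and 4, 139 without female PiC-MeA replicate 3, 136, 21 and 25 without male PiC-MeA replicates 1, 2 and 3, and 16 without the 3 PiC-PrL libraries with the fewest genes. DESeq2 called 1476 higher and 546 lower, voom 2172 higher and 445 lower, and edgeR fitted to the male groups only 786 higher and 201 lower.

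Within females no gene passed between the projections. Prune2 (log2 -2.40 ± 0.42) and Gnb1 (-1.65 ± 0.29) had the smallest adjusted p of 0.204, and Zbtb20 stood at 13.5 ± 4.32 CPM in PiC-MeA and 326 ± 368 CPM in PiC-PrL neurons (adjusted p = 0.294). Pex3, a peroxisome assembly protein, and Pfn4 had 0 counts in every female PiC-PrL library and were at least 136-fold and at least 105-fold higher in female PiC-MeA neurons (adjusted p = 0.370). Inhibitory neuron markers (median -2.39 over 22 members, camera adjusted p = 5.66e-05, adjusted p = 0.212 with an estimated correlation) and astrocyte markers (median -1.36 over 18, camera adjusted p = 6.85e-05, adjusted p = 0.162 with an estimated correlation) ranked lower in PiC-MeA neurons. So did growth factor and MAPK signalling genes (median -0.61 over 43, camera adjusted p = 0.00383, adjusted p = 0.0629 with an estimated correlation), with Nras, Dusp3, Spry2 and Gsk3b lower adjusted over the list alone. Among inhibitory markers, Gad1 stood at 914, 37.4, 49.6 and 314 CPM of total counts in female PiC-PrL replicates 1 to 4. Npy stood at 1549, 13.6, 115 and 3081 CPM, so the levels of these markers differed widely between tubes of 1 group. By edgeR 0 genes passed, 1619 had an unadjusted p under 0.05, DESeq2 called 628 and voom 31. The count was 1 without female PiC-PrL replicate 1 or male PiC-MeA replicate 1. Whether males and females differ in the projection effect is the difference between the sex differences given above, for which no gene passed.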

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

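The tests of depth, of genomic DNA or unspliced RNA and of gene span below, and the family of 20 exact tests, were chosen only after the result was seen. Measures were tested 1 at a time within female and within male PiC-PrL libraries, 4 libraries each. Of 125 such tests 19 found a library far from the other 3 by Dixon's criterion. In 10 of the 19 the other 3 libraries were at 0, where any count is flagged by construction, so the number flagged is not set against chance.

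The number of genes with a count had a sex difference in PiC-MeA neurons that exceeded the one in PiC-PrL neurons by 6365 genes (exact permutation p = 0.00286, adjusted p = 0.0571 over 20 tests). For genes with at least 10 counts the difference was 5120 (exact permutation p = 0.0229, adjusted p = 0.0952). Both p-values come from moving sex labels within each projection. They are for no sex difference in either projection and do not single out unequal ones. Male PiC-MeA libraries had 14157 to 15517 genes at 10 counts, against 7619 to 10819 in the other 11 libraries.

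Counts for more genes in every male PiC-MeA library than in any other library were weighed against technical explanations. Greater depth is argued against: these libraries hold the smallest totals, and after thinning every library to 6132985 counts the lowest of them still exceeded the highest other library by 4677 genes. Reads from genomic DNA or unspliced RNA may contribute, since after thinning 16.3% to 24.0% of olfactory receptor genes, which encode the odour receptors of the nose, had a count in male PiC-MeA libraries and 1.61% to 4.30% in the others, a ratio of at least 3.79. A batch that the labels do not record, RNA from cells of other types and a true difference of male PiC-MeA neurons stay open, and the last was not tested.

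The lower ranks of 3 gene lists in male than in female PiC-MeA neurons were weighed against a trend with gene span that differs between libraries. Once the trend was removed, 33.2% of the drop in the median of cytosolic ribosomal proteins was left (approximate error 8.31), so gene span may account for most of it. For the oxidative phosphorylation list 52.2% was left (error 11.9) and for the proteasome 72.1% (error 9.85), values that leave the share of gene span open. These errors take the members of a list as independent and leave out the spread between libraries. With the uncentred removal, which put the median of all genes at -0.75 in this contrast, the drops came to 111%, 139% and 164% of their size, and to 13.6%, 33.8% and 82.0% once measured relative to all genes. A difference between male and female neurons was not tested apart from this trend and stays open.

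In single libraries, the mitochondrial share of counts was 12.2% in female PiC-PrL replicate 2, above 4.57% to 5.68% in the other 3, and its mt-Cytb level was 79795 CPM. Opcml stood at 623 CPM in female PiC-PrL replicate 4, above 172 to 213 in the others, and Esr1 at 55.6 CPM in female PiC-PrL replicate 3, with at most 0.921 in the others. In male PiC-PrL libraries Nras stood at 976 CPM in replicate 2, against 407 to 436, Eif2s3y at 178 CPM in replicate 4, against 66.1 to 82.2, and Uty at 24.6 CPM in replicate 1, against at most 0.407. Lrp1b was lowest in male PiC-PrL replicate 3, at 340 CPM against 521 to 555, and so was Ddx3y, at 0.626 CPM against 77.1 to 86.6. The other cases were levels near 0 beside libraries at 0. These were Cln8 and Selenon in female PiC-PrL replicate 2 (0.0921 and 0.184 CPM), Kdm5d in female PiC-PrL replicate 4 (0.0702 CPM), and in male PiC-PrL libraries Mex3c (2.05 CPM), Ptpn21 (0.128 CPM), Zfp455 and Cyp19a1 (both 0.0641 CPM) in replicate 1, Ifit1 (0.0815 CPM) in replicate 2, and Pfn4 (0.0695 CPM) and Zfp758 (0.139 CPM) in replicate 3.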

How the results depend on the processing

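The gene span alternatives and those without the 3 male PiC-MeA libraries or without the 3 PiC-PrL libraries with the fewest genes were chosen after seeing the data, and the other alternatives before. Of the 39 calls of named genes, 16 were kept with any 1 library left out and 23 ended in at least 1 such fit. By setting, 39 were kept with DESeq2, 37 with voom, 36 with no filter, 33 with DESeq2 size factors, 33 without the robust option, 30 with the span trend removed, 36 with the uncentred removal, 28 of 32 with the stricter filter, 15 with the replicate block, 14 without the few-gene PiC-PrL libraries and 0 with the detected-gene covariate. The covariate moves with the male PiC-MeA libraries and widened errors, for Gnb1 from 0.21 to 0.85 around a log2 that went from -2.14 to -1.31. Except where stated, the cause of a change was not tested. Depth limits genes with few counts: at the smallest total a count of 0 allows 0.489 CPM.

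For genes differing between male and female PiC-PrL neurons (0), the count was 38 with no filter, 1 with the stricter filter, 1017 with DESeq2, 8 with voom, 1 without the robust option, 1 with the uncentred span removal and 0 to 1 with any 1 library left out. For gene lists differing between male and female PiC-PrL neurons (6), it was 17 with no filter, 3 with voom, 1 with the covariate, 0 with an estimated correlation, 2 with fry, 2 with the span trend removed, 2 uncentred, 10 without male PiC-MeA libraries, 1 without the few-gene libraries and 3 to 11 in single omissions. For genes differing between male and female PiC-MeA neurons (0), it was 45 with no filter, 777 with DESeq2, 1761 with voom, 1 with the span trend removed, 56 uncentred (3 higher, 53 lower) and 0 to 14 in single omissions. For gene lists differing between male and female PiC-MeA neurons (11), it was 1 with the covariate, 0 with an estimated correlation, 17 uncentred and 10 to 14 in single omissions.

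For genes differing between males and females, averaged over both projections (2), the count was 17 with no filter, 1 with the stricter filter, 631 with DESeq2, 4 with voom, 0 with the covariate, 1 with the replicate block, 1 without the few-gene libraries and 1 to 2 in single omissions. For genes whose sex difference differs between the projections (0), it was 84 with no filter, 1175 with DESeq2, 729 with voom, 1 with the span trend removed, 101 uncentred (3 and 98) and 0 to 5 in single omissions. For genes differing between PiC-MeA and PiC-PrL neurons of females (0), it was 46 with no filter, 628 with DESeq2, 31 with voom and 0 to 1 in single omissions. For genes differing between PiC-MeA and PiC-PrL neurons of males (88), it was 159 with no filter, 2022 with DESeq2, 2617 with voom, 987 with only the groups compared, 0 with the covariate, 38 with the block, 1275 uncentred (114 and 1161), 16 without the few-gene libraries and 20 to 139 in single omissions.

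For genes differing between PiC-MeA and PiC-PrL neurons, averaged over both sexes (120, 28 higher and 92 lower), the count was 452 with no filter (289 and 163), 75 with the stricter filter (6 and 69), 1492 with DESeq2 (961 and 531), 1277 with voom (1027 and 250), 0 with the covariate, 43 with the block (3 and 40), 1455 uncentred (352 and 1103), 31 without the few-gene libraries (3 and 28) and 39 to 128 in single omissions. DESeq2 size factors gave 83 (15 and 68). For gene lists differing between PiC-MeA and PiC-PrL neurons, averaged over both sexes (8), it was 13 with no filter, 1 with the covariate, 0 with an estimated correlation, 13 with the span trend removed, 17 uncentred, 13 without the few-gene libraries and 8 to 12 in single omissions.

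Fitted log2 changes of these named genes turned in direction. For sex in PiC-PrL neurons Uty was -0.40 without male replicate 1 (highest omission value 5.36), Esr1 0.21 without female replicate 3 (lowest -4.97), Pgr -0.28 without male replicate 4 (highest 2.21) and -0.12 without the few-gene libraries, Cyp19a1 0.073 with the covariate, and Nr3c1 -0.28, -0.08 and -0.23 without female replicates 2 and 3 and male replicate 3 (highest 0.56). In PiC-MeA neurons the covariate gave Uty -2.57, Esr1 -5.05, Pgr -2.62 and Nr3c1 -7.53, and the uncentred span removal gave Esr1 -0.48 and Pgr -0.52, where the median of all genes was -0.75. Pgr was -0.011 without male PiC-MeA replicate 3 (highest 1.201), and Nr3c1 was -0.04 without female PiC-MeA replicate 2, -0.19 without male PiC-MeA replicate 3 (highest 0.49) and -0.43 with the span trend removed. With sex_MeA written for male minus female PiC-MeA neurons, the uncentred removal gave -1.44 as the log2 fold change of Nr3c1, sex_MeA, and -0.060 as the log2 fold change of Lrp1b, sex_MeA. In the average projection contrast the covariate gave mt-Cytb 1.62, Rps14 0.14, Sdhb 0.10, Uqcrq 0.081, Ndufb8 0.74, Psmb6 1.197 and Zfp455 -1.04, with errors of 0.85 to 2.16.

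The median log2 of all genes was computed for DESeq2 size factors and both span removals alone. Size factors moved it by less than 0.1 in each of the 7 contrasts. So did the centred removal, except for the difference between the sex differences, where it went from 0.31 to 0.19. Uncentred, it went from -0.02 to 0.19 for sex in PiC-PrL, from 0.12 to -0.75 for sex in PiC-MeA, from 0.04 to -0.25 for sex on average, from 0.31 to -0.83 for the difference of sex differences, from -0.06 to -0.39 for projection in females, from 0.16 to -1.28 in males and from 0.07 to -0.79 on average.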

Other observations

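The tests of male PiC-MeA libraries alone and of gene span below were chosen only after the result was seen, and the splits of the samples and the test of 3' UTR length before. Averaged over both projections, astrocyte markers were positive in males for 14 of 18 members (median 1.06, camera adjusted p = 8.3e-05, adjusted p = 0.315 with an estimated correlation), and Slc1a2, Slc4a4, Aldoc, Gjb6, Slc1a3 and Aqp4 passed adjusted over the list alone. Immediate early genes were negative in 24 of 30 (median -0.64, camera adjusted p = 0.000151, adjusted p = 0.315 with an estimated correlation). X-linked genes that escape inactivation, which cells with a second X chromosome can express from both copies, were negative in males for 7 of 7 members (median -0.84, camera adjusted p = 0.0330, adjusted p = 0.315 with an estimated correlation), and 0 passed adjusted over the list alone. In PiC-PrL neurons 7 of 7 were negative (median -1.43, camera adjusted p = 0.0625) and in PiC-MeA neurons 4 of 7 (median -0.24, camera adjusted p = 0.509). The sex difference of inhibitory neuron markers differed between the projections by a median of 4.75 over 22 members (camera adjusted p = 0.000325, adjusted p = 0.337 with an estimated correlation), beside the larger number of genes detected in male PiC-MeA libraries. Of total counts, the neuropeptide Npy averaged 1190 CPM in female PiC-PrL libraries with an SD of 1443, and 21.5, 7.48 and 11.3 CPM in male PiC-PrL, female PiC-MeA and male PiC-MeA libraries. Female PiC-PrL replicates 1 to 4 stood at 1549, 13.6, 115 and 3081 CPM of Npy and 914, 37.4, 49.6 and 314 CPM of Gad1. The PiC-PrL side of the inhibitory marker result thus rests in part on female replicates 1 and 4, and cell content of the tubes was not tested apart from sex.

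Within males, proteasome subunits were lower in PiC-MeA neurons for 34 of 37 members (median -1.16, camera adjusted p = 9.03e-16, adjusted p = 0.0648 with an estimated correlation). Of these 2 fell over all genes, and adjusted over the list alone 15 were lower and 1 higher. Oxidative phosphorylation genes were negative in 73 of 85 (median -1.07, camera adjusted p = 4.37e-25, adjusted p = 0.0648 with an estimated correlation), with 4 falling over all genes and 31 lower and 2 higher adjusted over the list alone. Mitochondrially encoded genes were positive in 30 of 32 (median 1.345, camera adjusted p = 0.0308, adjusted p = 0.574 with an estimated correlation). Neuromodulator receptors were positive in 37 of 53 (median 2.11, camera adjusted p = 0.0292, adjusted p = 0.0648 with an estimated correlation), with Oprm1, the mu opioid receptor, Drd3 and Htr7 past the threshold adjusted over the list alone. Of total counts, the microglia marker Cx3cr1 ranged from 0.467 to 101 CPM over the 14 libraries. The vessel gene Flt1 was at 5.11, 9.51 and 44.4 CPM in male PiC-MeA libraries and at most 0.753 in any other library. Another vessel gene, Cldn5, and another microglia marker, P2ry12, were at 0 in all 14 libraries.

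Other splits of the same samples were refitted to see how often they give as many calls. For projection averaged over both sexes 1 of 100 splits, the real one, gave as many as 120 genes and the highest other gave 4. For projection in males 1 of 35 did, the smallest share that 35 splits can give, with 88 genes against 1. The margins of both projection counts argue against chance. For sex averaged over both projections 1 of 100 did, with 2 genes against 1. That margin of 1 gene does not settle chance, since the real count was itself 1 in 11 of 14 single-library omissions. A count of 0 is reached by every split, so the splits decide nothing for sex in PiC-PrL (35 of 35 splits, highest other 3), for projection in females (35 of 35, highest other 1) and for the difference between the sex differences (100 of 100, highest other 1). Chance is not excluded for the 6 lists of sex in PiC-PrL (4 of 35, highest other 10) and the 8 lists of projection on average (10 of 100, highest other 11). Sex in PiC-MeA has only 10 splits, too few for a share under 0.05: the real counts were 0 genes and 11 lists, the highest others 0 and 14, and 10 and 2 splits reached the real counts.

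Among genes differing between PiC-MeA and PiC-PrL neurons, averaged over both sexes, more were called lower than higher with edgeR (92 against 28), as with the stricter filter (69 against 6) and the replicate block (40 against 3). The balance turned within edgeR with no filter (163 lower, 289 higher) and at an unadjusted p under 0.05 (770 lower, 1773 higher), and DESeq2 and voom called more higher than lower (961 against 531 and 1027 against 250). The excess of lower calls therefore depends on the filter, the threshold and the test. Male PiC-MeA libraries alone are argued against for the direction of the genes called lower in males. Of the 88 genes called in males 71 (80.7%) had the same direction in females, where 49.1% of all genes, not matched for level, did. This agreement rests on the lower genes, of which 67 of 78 were lower in females. Their medians were -2.19 in males and -0.70 in females, where no gene passed. A share of the male libraries in the size of the changes and in the calls therefore stays open. Gene span as the whole cause is argued against, since 70 of the 92 genes were still called lower with the trend removed (median -1.79 before and -1.81 after), and 3' UTR length is argued against by a ratio of medians of 1.15 to genes of like level (1789 against 1553 bases, 87 genes, permutation p = 0.370 over 10000 draws). A link with the number of genes detected stays open. The covariate for it moves with the male PiC-MeA libraries and widened errors, so its 0 calls decide nothing. With it the log2 change of Dusp3 went from -2.41 ± 0.23 to -1.78 ± 0.84, of Nras from -2.05 ± 0.30 to -2.49 ± 1.246 and of Gsk3b from -1.95 ± 0.29 to -0.62 ± 1.204, and 91 of the 120 genes kept their direction. The projection itself, which may underlie the pattern, and a batch that the labels do not record stay open and were not tested apart from each other.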
